A study of Oryza sativa with 32 samples.

How the data were processed

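Leaf RNA of 32 rice samples was measured on 16 Agilent 2-colour arrays, with 4 arrays on each of 4 slides, from 200 ng of total RNA per sample. Per the labels, each sample was one dye of one array, and the deposited files of the samples that shared an array were identical. Koshihikari leaves of 28 and 49 days past sowing shared 13 arrays, 12 clock times and a second 10:00 array on another slide, with the dyes alternating between arrays. Nipponbare (Cy3) and Kasalath (Cy5) shared 3 arrays of 28-day leaves. Slides 1, 2 and 3 held the Koshihikari arrays from 10:00 to 16:00, from 18:00 to 0:00 and from 2:00 to 8:00, and slide 4 held the second 10:00 array and the other varieties. The labels give 1 sample per stage and time, apart from 10:00. They do not say whether the second 10:00 sample or the samples of other times came from separate plants. The p-values therefore measure the spread around each fitted curve or mean difference. That spread can hold departure from a 24 h curve, change of a difference with time of day and technical variation, besides variation between samples.

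The deposited scanner files hold intensities on a linear scale, made by the authors with Agilent Feature Extraction version 10.5.1.1, per the submitters' processing notes and the file headers. Mean signal intensity and background intensity are unprocessed spot brightness, per the file headers, and the processed signal intensity was background-subtracted with spatial detrending and dye-normalized within each array by the same software. The headers give the probe coordinates as unmapped, so no coordinates are printed. The deposited value table of 13005 genes also holds intensities on a linear scale. It gives gene identifiers of the Rice Annotation Project and no probe. Its values equalled, within a relative tolerance of 1e-06 on all 32 samples, the processed signal of exactly 1 probe for 11074 genes the mean of 2 probes for 1476 genes and the mean of 3 or more for 213, and this match gave the probes of 12763 genes (98.1%). Its scale and direction were settled by that match, and it was not centred or scaled between arrays, its column medians being between 259.9 and 696.1. The other 242 genes had no matched probe and were read only from the authors' value table, which is named where that was done. How the authors chose probes is not given in the sources used here. Of 151878 non-control probes, 137184 belonged to no gene of the value table.

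Mean and background signals were corrected by normexp with an offset of 50, log ratios were normalized by loess within arrays with control spots and outlier spots at weight 0, and average intensities by Aquantile between arrays, in limma 3.58.1 under R 4.3.3. Probes well above background in at least 3 of 32 channels were kept, and probes of a gene were averaged on the log2 scale, which left 11019 genes, of which 9 had a missing value on some array. Per sample, the median mean signal was between 78.98 and 251.11 and the median background between 22.0 and 69.0. For a gene not well above background in any sample of a group, the fold is given as at least the ratio of the bright group's mean to the mean of, per sample, the higher of the gene's own value and the lowest value among probes well above background.

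Each comparison was fitted with lmFit and eBayes and adjusted by the Benjamini-Hochberg method at 0.05. Rhythm was a moderated F test of a cosine and a sine of 24 h on the mean of the 2 channels of the 13 Koshihikari arrays, which is free of stage and dye, and the peak-to-trough range is that of the fitted curve. Stage was tested on log ratios with a dye term, and its dependence on time with stage-signed cosine and sine. Kasalath minus Nipponbare was tested over all 16 arrays with the dye effect of each gene learned from Koshihikari. That comparison took its spread mostly from the 13 Koshihikari arrays and less from the 3 variety arrays. With 1 sample per variety and time, its dependence on time was tested against the spread of the Koshihikari arrays, the lone samples being assumed to vary like them. Nipponbare minus Koshihikari used the 3 time-matched Cy3 differences.

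Before the data were examined, the samples of each group, the tests, the alternatives, the rule for naming genes and 18 lists of 191 genes were fixed. Of these identifiers 131 were in the value table and 111 had a matched probe. The files do not pair identifiers with gene names. Names are those of the fixed lists, written from general knowledge of the identifiers, and they are printed only for the 67 list members in the value table whose name the RefSeq annotation ASM3414082v1 also holds on the same chromosome. Every one of 230 pairs of such names on a chromosome was in the same order by identifier and in RefSeq. This check does not prove each pairing. The other 59 members, whose names were not found there, and 5 found on another chromosome were counted in their lists without a name. The rule named every clock gene, up to 3 called members of each other list and the called genes of largest range for rhythm, and for the other comparisons the 5 largest rises and 5 largest falls, up to 3 called members of each list, and the clock and flowering groups. Members without a checked name stayed unnamed, and at most 2 identifiers in each direction, the called genes of largest difference outside the lists that were well above background in at least 50% of the samples compared, are printed per comparison. Genes named for curves that differ between stages are the named list members that passed that test, and the members read from the value table were chosen after their values were seen. Lists built on description text were not run, since the files hold no descriptions.

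Lists with at least 3 tested members were tested by Fisher's exact test for rhythm and by camera with a preset correlation of 0.01, repeated with the estimated correlation, for the other comparisons, with adjustment over 14 lists within each comparison. The vascular, cell division and gibberellin lists had fewer tested members. Of their members, CESA7 was called for stage and CDKB2;1 for stage by time, 1 of 2 gibberellin genes was called for rhythm and 1 of 2 was lower at 49 days, and none of the 4 was called between varieties. The list of variety loci had no member in the value table.

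The fits, which had been run once on the real data beforehand, were tested on simulated data of 11010 genes with residual spread taken from the real data, 100 genes being changed at each size. A rhythm of log2 range 1 was recovered in 67% and of range 2 in 89% of the changed genes. A stage difference of 0.5 was recovered in 79% and of 1 in 99%. A stage-by-time curve of 1 was recovered in 64% and of 2 in 89%, and a Kasalath difference of 1 in 70% and of 2 in 93%. A Kasalath difference by time of 1 was recovered in 1% and of 2 in 26%, and a Nipponbare minus Koshihikari difference of 1 in 35% and of 2 in 78%. Between 3.4% and 6.8% of the calls were of unchanged genes. None of 20 lists of unchanged genes was called by either list test. The simulated noise was independent between genes and arrays, with no slide effect and no correlation within lists. For stage and Kasalath, its spread came from a Koshihikari fit with stage-signed time terms, which the real tests of these differences leave out. The variety arrays were given that same spread. Lists of unchanged genes held few called genes, so Fisher's test could hardly call them. These rates therefore do not cover data with slide effects or correlated genes, or stage and variety differences that change with time, for which they may be too high.

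The alternatives were the software's processed signals, median centring in place of loess, average intensities centred in place of Aquantile, no filter and a filter on all 32 channels, the brightest probe per gene, the authors' value table, the second 10:00 array left out, slide as a block or slides taken alone, 24 h with 12 h harmonics, a separate-channel model, each stage alone, no dye term, and each variety sample left out in turn. Text files were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.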

Results

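Transcript levels in rice leaves were measured around the clock in a growth chamber, with 2-colour arrays that carried 1 sample per dye. Leaves of the japonica variety Koshihikari were taken every 2 h, at 12 clock times, from plants 28 and 49 days past sowing, and the 10:00 time was sampled a second time, which gave 13 samples per stage. Nipponbare, another japonica variety, and Kasalath, of the aus group, were sampled at 14:00, 22:00 and 6:00 at 28 days, with 3 samples each. A sample was the youngest fully expanded leaf of 3 plants. Lights were on from 8:00 to 22:30 at 450 µmol photons per square metre per second, with 28 °C by day and 24 °C by night. In each of the 32 samples 52.4% to 62.4% of the gene and other non-control probes stood well above background, and no probe was saturated. The number of arrays, 13 for Koshihikari and 3 for the other varieties, limits the precision of each value below. Values after ± are standard errors from the limma fit, and differences are on the log2 scale.

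The first question was which transcripts followed a 24 h cycle in Koshihikari leaves. All 9 tested genes of the circadian clock list cycled, and their peaks were spread from 4.2 h to 22.2 h clock time. OsCCA1/LHY (Os08t0157600), a morning transcription factor of the central oscillator, peaked at 9.2 h with a peak-to-trough range of 7.38 ± 0.16 (166-fold, adjusted p = 1.7e-10, n = 13 arrays). OsPRR95 (Os09t0532400), a pseudo-response regulator, peaked at 16.0 h with a range of 8.84 ± 0.87 (459-fold, adjusted p = 1.39e-05). OsGI (Os01t0182600), the rice GIGANTEA gene, peaked at 19.4 h with a range of 5.67 ± 0.67 (50.9-fold), and the pseudo-response regulator OsPRR1/TOC1 (Os02t0618200) peaked at 19.5 h with a range of 5.88 ± 0.26 (58.9-fold). OsLUX/PCL1 (Os01t0971800), a component of the evening complex, peaked at 22.2 h with a range of 8.94 ± 0.60 (492-fold). The largest fitted range on the clock list, 9.32 ± 0.63 or 641-fold with a peak at 6.5 h, belonged to Os02t0685200. Some of these troughs lay near background. OsPRR95 was well above background in 28 of 32 samples, OsPRR1/TOC1 and Os02t0685200 in 30 each and OsLUX/PCL1 in 31. Their ranges and folds, and the order among them, therefore depend on the floor and the offset. Outside the lists Os07t0529600 had a range of 9.23 ± 0.75 (600-fold) with a peak at 19.6 h. A pair of clock genes could be read only from the authors' value table, where OsPRR37 had a range of 5.30 ± 0.99 with a peak at 18.0 h and OsPRR73 a range of 6.39 ± 1.5 with a peak at 17.0 h.

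**Figure D1:**
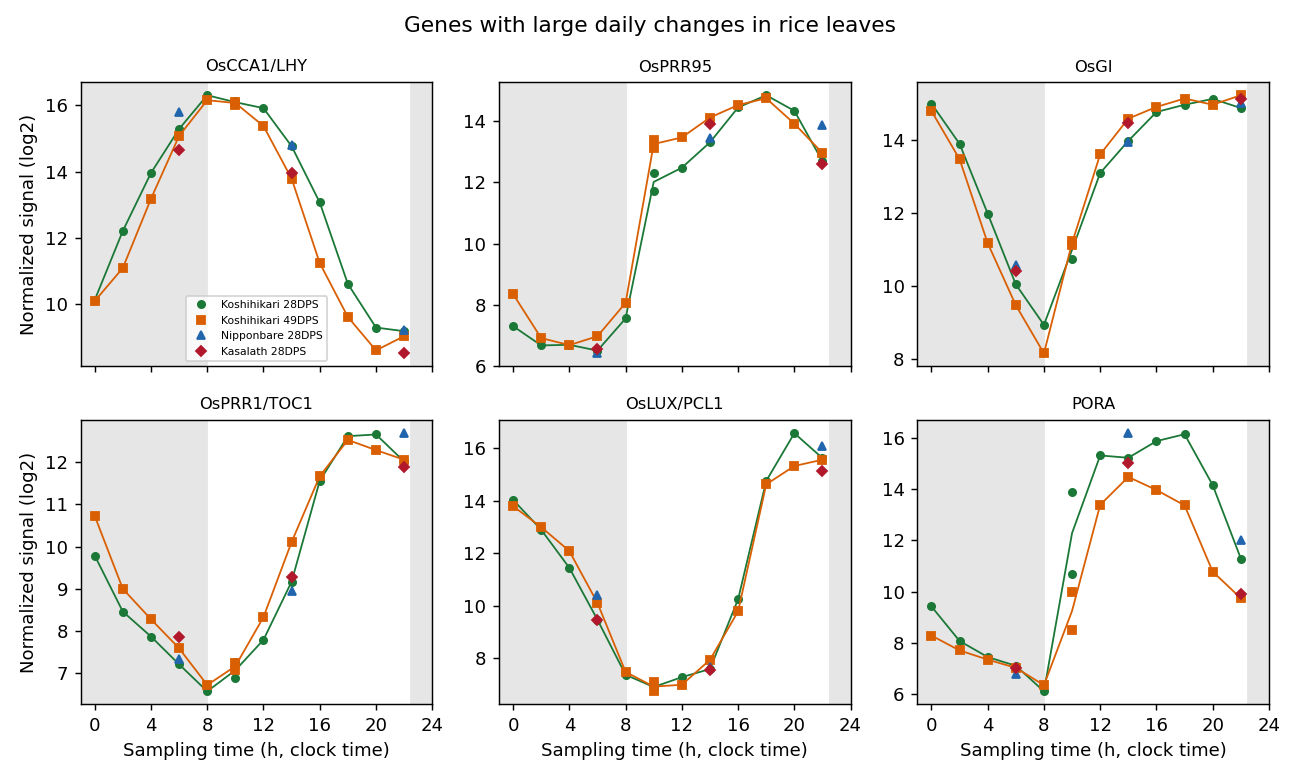
Normalized log2 signal (vertical axes) of 6 named genes against clock time in hours (horizontal axes), 1 point per sample, with lines through the Koshihikari means at 28 and 49 days past sowing and the dark period in grey. OsCCA1/LHY is highest near its fitted peak at 9.2 h, OsGI near 19.4 h and OsLUX/PCL1 near 22.2 h, and the 3 Nipponbare and 3 Kasalath samples are drawn at 6, 14 and 22 h.

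Genes of pigment synthesis and light harvesting cycled widely. All 7 tested members of the chlorophyll synthesis list and 7 of 8 light-harvesting antenna genes passed the test. PORA (Os04t0678700), which makes chlorophyllide in the light, ranged over 8.71 ± 0.82 (418-fold) and peaked at 16.1 h. It was well above background in 29 of 32 samples, so its trough lay near background and its fold depends on the floor. CHLH (Os03t0323200), a magnesium chelatase subunit, ranged over 4.13 ± 0.30 (17.5-fold) with a peak at 13.8 h, and DVR (Os03t0351200), a divinyl reductase of the same pathway, over 1.85 ± 0.19 with a peak at 15.1 h. The antenna genes that cycled had ranges from 1.02 to 5.53, and their peaks were spread from 8.4 h to 23.4 h. In the authors' value table the antenna gene CAB1R ranged over 9.52 ± 1.48 with a peak at 15.9 h.

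Nitrogen, redox and senescence genes also cycled. All 4 nitrogen genes passed, led by nitrate reductase NIA1 (Os08t0468100) with a range of 3.95 ± 0.92 (15.4-fold) and a peak at 12.8 h, and with cytosolic glutamine synthetase GS1;1 (Os02t0735200) at 1.47 ± 0.28 and plastid glutamine synthetase GS2 (Os04t0659100) at 0.83 ± 0.20. All 5 redox genes passed, and the catalase genes CATA (Os02t0115700, 4.40 ± 0.51, 21.2-fold) and CATB (Os06t0727200, 1.66 ± 0.13) peaked at 19.0 h and 19.7 h. All 4 senescence genes passed, among them the chlorophyll b reductase NYC1 (Os01t0227100), with a range of 2.27 ± 0.22 and a peak at 20.5 h, and Osl2 (Os04t0614600), with 1.07 ± 0.16 and a peak at 3.8 h. Of the heat stress list 2 of 4 passed, and the heat shock factor HSFA2d (Os03t0161900) ranged over 4.25 ± 0.21 (19.0-fold) with a peak at 12.1 h. Of the phenylpropanoid list 2 of 4 passed, with phenylalanine ammonia-lyase PAL (Os02t0627100) at 2.78 ± 0.55 (6.87-fold) and a peak at 11.8 h.

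Flowering genes cycled too. All 7 tested members passed, with ranges from 0.24 to 3.05. Among them OsMADS50 (Os03t0122600), a promoter of flowering, ranged over 1.21 ± 0.10 with a peak at 6.2 h, Hd3a (Os06t0157700), the rice florigen gene, over 1.88 in the 49-day samples alone (adjusted p = 0.000484), with no call at 28 days, where it was near background (0.31, adjusted p = 0.676), and Ehd2/RID1 (Os10t0419200), a zinc finger regulator of flowering, over 0.81 ± 0.13 with a peak at 5.5 h. Of the photoreceptor and chromophore list 6 of 9 passed. SE5 (Os06t0603000), needed for the phytochrome chromophore, ranged over 2.64 ± 0.16 (6.24-fold) with a peak at 9.6 h, and phytochrome B, PHYB (Os03t0309200), over 1.31 ± 0.18 with a peak at 22.4 h. Of the Calvin cycle list 7 of 10 passed with ranges of at most 1.28, and of the starch and sucrose list 10 of 16, including the sucrose transporter SUT1 (Os03t0170900, 1.18 ± 0.17, peak at 5.0 h). Of the defence list 4 of 11 passed, including NH1 (Os01t0194300), the rice NPR1 gene, at 1.23 ± 0.25. Of the drought and cold list 1 of 5 passed.

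Across all genes, limma's moderated F test of a 24 h curve called 7392 of 11019 tested genes (67.1%), and 3151 of them had a range of at least 2-fold. The most peaks, 745, fell between 18 and 20 h and the fewest, 381, between 14 and 16 h. None of the 14 tested lists passed Fisher's exact test, one-sided, for an excess of called genes, although 6 lists were called in full. The lowest adjusted p was 0.285, given by the clock (9 of 9), chlorophyll synthesis (7 of 7) and flowering (7 of 7) lists, and the clock list had an unadjusted p of 0.0275. Adjusted over the list alone, the number of called members was the same in every list except photoreceptors, where it was 7. When only ranges of at least 2-fold were counted, a criterion chosen after seeing the data, 4 lists stood out by the same test: clock (9 of 9, adjusted p = 0.000178), antenna (7 of 8, 0.00654), chlorophyll synthesis (6 of 7, 0.0134) and senescence (4 of 4, 0.0234). Consecutive times shared a slide, and slide as a fixed block left 4778 called genes, of which 4150 were also called without it. Under that block 1 of the 9 clock genes, with its peak at 4.2 h, was not called (range 0.81 ± 0.25, adjusted p = 0.0632). PAL (2.60 ± 0.82, adjusted p = 0.0671), GS2 (1.03 ± 0.32, 0.0658) and the starch-degrading enzyme DPE2 (1.26 ± 0.47, 0.12) kept ranges near their former ones with errors that were larger or alike, and were not called. The ascorbate peroxidase APX2 shrank from 2.31 ± 0.59 to 0.23 ± 0.46 (0.905), NH1 to 0.62 ± 0.27 (0.196), Osl2 to 0.71 ± 0.24 (0.0911), PBZ1 to 0.43 ± 0.55 (0.79) and DREB2A to 0.21 ± 0.14 (0.459), and the Calvin cycle gene RPE was at 0.42 ± 0.22 (0.277). With slide as a random block 5716 genes were called, at a within-slide correlation of 0.527, and the curve was not tested within single slides.

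**Figure D2:**
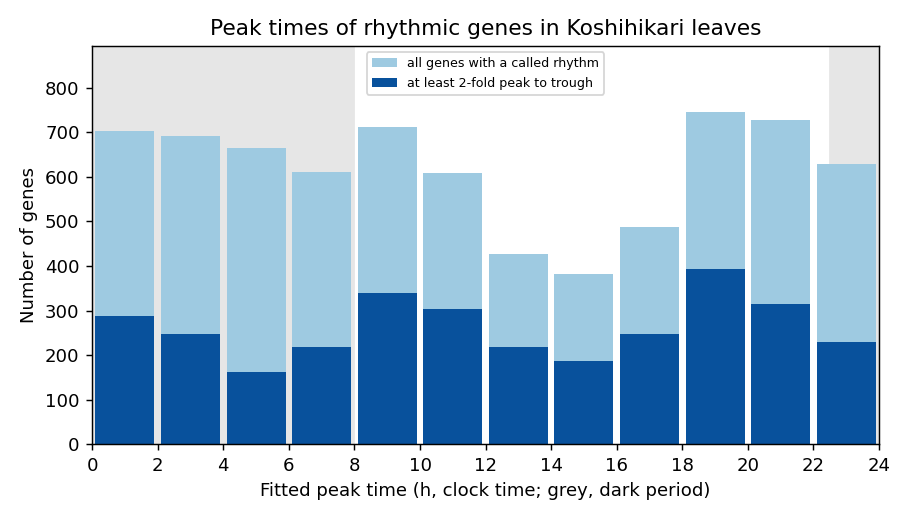
Number of genes with a called 24 h rhythm in Koshihikari leaves (vertical axis) by fitted peak time in 2 h bins of clock time (horizontal axis), with genes of at least 2-fold range in the darker colour and the dark period in grey. The bin from 18 to 20 h holds 745 genes and the bin from 14 to 16 h holds 381.

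The second question was how leaves of 49-day plants differed from those of 28-day plants, with each pair of stages on 1 array. Photosynthesis genes were lower and defence genes higher at 49 days. All 8 antenna genes with a matched probe fell, with a median of -1.64 (of the 6 others, in the authors' value table, 5 fell and 1 was not called, at -0.53 ± 0.27), as did all 10 Calvin cycle genes, with a median of -1.13, and 6 of 7 chlorophyll synthesis genes, with a median of -1.34 over the list. Of 11 defence genes 10 rose, with a median of 1.26. In the authors' value table SALT, of the drought and cold list, was at -2.55 ± 0.38 (adjusted p = 1e-04). Among named genes with a matched probe, the largest falls were those of nitrate reductase NIA1, at -1.77 ± 0.27 (3.41-fold lower, adjusted p = 9.81e-05, lower in 12 of 13 arrays), the secondary wall cellulose synthase CESA7 (Os10t0467800), at -1.59 ± 0.61 and well above background in 5 of 13 samples at 49 days against 12 of 13 at 28 days, PORA, at -1.51 ± 0.35, and CHLH, at -1.34 ± 0.22. The size of the CESA7 fall, and its place in this order, depend on the floor. The ribulose-phosphate epimerase RPE (Os03t0169100) of the Calvin cycle fell by 1.12 with a standard error of 0.16.

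Among the rises, PBZ1 (Os12t0555500), a pathogenesis-related gene, was higher at 49 days by 2.05 ± 0.18 (4.13-fold, adjusted p = 7.33e-07, higher in 13 of 13 arrays), and NH1, a regulator of salicylic acid responses, by 1.26 ± 0.10 (2.40-fold, 13 of 13 arrays). TIFY11D (Os10t0392400), of the jasmonate repressor family, rose by 1.26 ± 0.43, PAL by 1.49 ± 0.39 and the cold-responsive regulator DREB1A (Os09t0522200) by 1.26 ± 0.51, the last in 9 of 13 arrays and with an adjusted p of 0.0453. Cytosolic GS1;1 rose by 0.90 ± 0.12 while plastid GS2 fell by 1.04 with a standard error of 0.15, and of 4 nitrogen genes 1 rose and 3 fell. Outside the lists, Os05t0202800 rose by 4.35 ± 0.32 (20.4-fold) and Os11t0170900 by 3.53 ± 0.32 (11.6-fold), and the differences of Os01t0368900 and Os03t0782200 were -4.87 ± 0.16 and -4.37 ± 0.99.

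Clock genes moved in both directions, and so did flowering genes before slide was taken as a block. Hd3a was higher at 49 days by 0.78 ± 0.16 (adjusted p = 0.00105, higher in 12 of 13 arrays), and it was well above background in 10 of 13 samples at 49 days against 1 of 13 at 28 days, so no exact fold is given. OsMADS50 rose by 0.45 ± 0.08 and Ehd2/RID1 by 0.29 ± 0.05, and of 7 flowering genes 3 rose and 2 fell. With slide as a fixed block neither fall was called (Hd16 at -0.11 ± 0.04, adjusted p = 0.0558, and the other at -0.47 ± 0.19, 0.0562). In the authors' value table OsMADS18, a gene of the flowering list, was higher at 49 days by 2.55 ± 0.08 (adjusted p = 1.9e-09). Of 9 clock genes 4 rose and 2 fell, with OsPRR95 at 0.48 ± 0.15 and OsCCA1/LHY at -0.59 ± 0.15. Over all arrays OsGI at -0.07 ± 0.12 and OsLUX/PCL1 at -0.06 ± 0.12 were not called. OsGI was called with opposite signs within slide 1, at 0.41, and within slide 3, at -0.65 ± 0.07 (adjusted p = 0.00548). These clock counts are those of the fit without a slide block. With slide as a fixed block 4 stage calls of named genes were lost. PHYB was lower by 1.71-fold (-0.77 ± 0.09), and 5 of 9 photoreceptor genes fell. Of the starch and sucrose list 3 of 16 rose and 7 fell, with SUT1 at 0.68 ± 0.10 and AGPS2 (Os08t0345800), a subunit of ADP-glucose pyrophosphorylase, at -0.79 ± 0.18. Of the redox list 3 of 5 rose and 1 fell, of the senescence list 2 of 4 rose and 1 fell, of the drought and cold list 1 of 5 rose and 1 fell, of the phenylpropanoid list 2 of 4 rose, and of the heat stress list 1 of 4 fell.

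**Figure D3:**
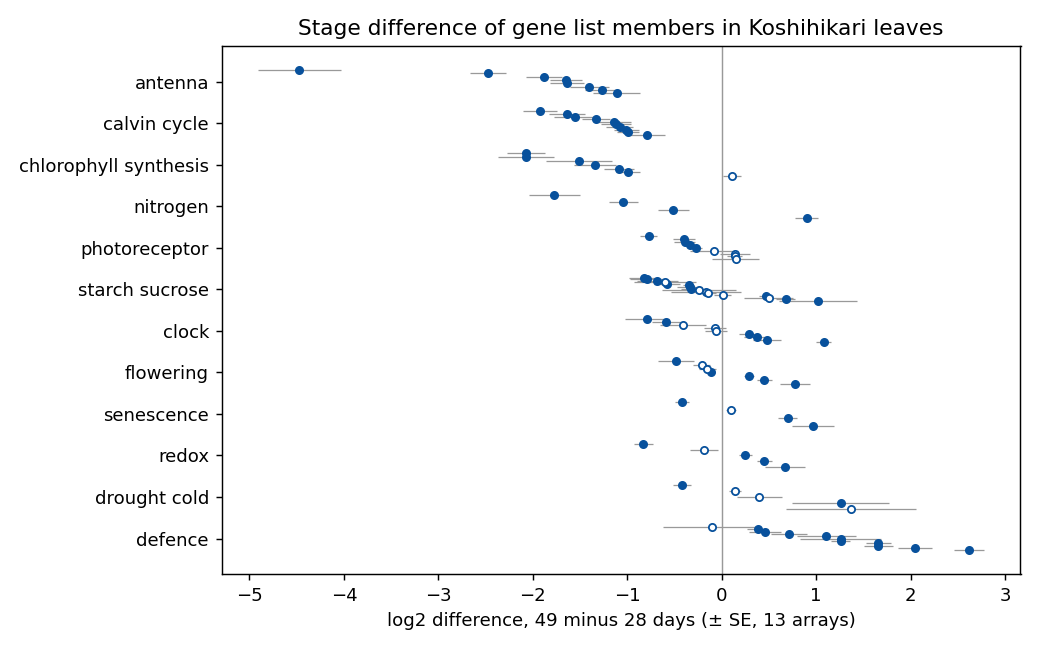
Difference between 49 and 28 days past sowing (horizontal axis, log2, with standard errors over 13 arrays) of each tested member of 12 gene lists (vertical axis), filled where the member was called and open where it was not. All 8 antenna and all 10 Calvin cycle members lie below 0, and the defence list has a median of 1.26.

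Limma called 6698 of 11019 genes between the stages, 3661 higher and 3037 lower at 49 days, and 374 and 466 of these by at least 2-fold. This balance of 2-fold changes turned with the scaling, to 875 higher and 748 lower on the scanner software's processed signals, 897 and 776 in the authors' value table and 787 and 306 with median centring. By camera with a preset correlation of 0.01 the antenna (adjusted p = 5.96e-05), Calvin cycle (3.69e-05), chlorophyll synthesis (0.00542) and defence (0.00128) lists were called, and no other list was. With an estimated correlation none of these 4 calls held, and each had an adjusted p = 0.298. Over the other 7 scaling and filter settings with the preset correlation, the 4 lists stayed called, with adjusted p of at most 0.000143, 0.00014, 0.0154 and 0.0291 in the same order. Of these settings, centring average intensities leaves the log ratios unchanged, so its agreement was fixed in advance. Adjusted over the list alone, 3 flowering genes were lower and no drought and cold gene was higher, and the counts of the other 12 lists were the same as over all genes. The medians kept their signs within each slide: antenna genes were at -2.06, -1.54 and -1.76 within slides 1, 2 and 3, Calvin cycle genes at -1.66, -1.30 and -0.73, chlorophyll synthesis genes at -2.12, -1.21 and -0.68, and defence genes at 1.31, 1.22 and 0.94. With slide as a fixed block the 4 medians were -1.72, -1.18, -1.38 and 1.23, and 6296 genes were called. Within slides 1, 2 and 3 the test called 4500, 1840 and 4831 genes. Median centring in place of loess moved the median difference of all genes from 0.02 to 0.26 and the share of calls that were higher from 54.7% to 74.2%, and it turned the flowering gene Hd16 (Os03t0793500) from -0.11 ± 0.04 to 0.28. The counts of rises and falls per list were made with loess, and with median centring 6 other named genes lost their call. Without the 12:00 array, a setting chosen after seeing the data, DREB1A (adjusted p = 0.0793) and OsPRR1/TOC1 (0.27 ± 0.11, 0.0606) kept similar sizes but were not called, and CESA7 was at -1.18 ± 0.55 (0.0813). CESA7 was also not called with slide as a fixed block (-1.49 ± 0.69, adjusted p = 0.0858) or without the second 10:00 array (0.0635), nor DREB1A on the processed signals (0.0776), with no filter (0.0526) or in the authors' value table (0.0825). Within slide 3, from 2:00 to 8:00, PORA was at -0.08 ± 0.10 (adjusted p = 0.565).

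The third question was whether the daily curve differed between the stages. Hd3a gave the clearest difference among named genes, with curves that differed by 1.58 from peak to trough (adjusted p = 0.00142) and the largest excess at 49 days at 10.4 h. The SOC1-like flowering gene OsMADS56 (Os10t0536100) differed by 0.87 with its largest excess at 4.6 h (adjusted p = 0.0128). Starch synthase SSI (Os06t0160700) differed by 2.41 with an excess at 2.7 h (adjusted p = 0.0151), and the sucrose transporter SUT2 (Os12t0641400) had its excess at 2.4 h (adjusted p = 0.018). CHLH differed by 1.93 (adjusted p = 0.0389), GS1;1 by 1.04 (0.0437), OsGI by 1.05 (0.0437), PHYB by 0.72 (0.0371) and the cell division kinase CDKB2;1 (Os08t0512600) by 0.83 (0.044). Curves of the other named clock genes did not pass this test, with OsCCA1/LHY at an adjusted p of 0.378 and OsPRR1/TOC1 at 0.786. Over the 2283 genes with a called range of at least 2-fold in each stage alone, the median shift of the peak, 49 minus 28 days, was -0.483 h (quartiles -1.06 and 0.158 h), and 1616 (70.8%) had the smaller range at 49 days. Neither the shift nor this share was tested or computed under another scaling, and the genes share arrays and slides.

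Limma called 819 genes for a stage difference that depended on time of day. The 49-day excess was largest between 0 and 4 h in 252 of them. With terms that let the stage difference vary by slide, no gene was called by limma, although 1433 genes had an unadjusted p below 0.05, and the curve difference of Hd3a (Os06t0157700) went from 1.58 ± 0.14 to 1.75 ± 0.29 (adjusted p = 0.192), while that of OsGI (Os01t0182600) went from 1.05 ± 0.23 to 0.07 ± 0.26 (0.987). Without the second 10:00 array OsGI at 1.06 ± 0.24 (adjusted p = 0.0519) and PHYB at 0.67 ± 0.16 (0.0578) were near their former sizes but not called. The count was 539 on the scanner software's processed signals and 489 in the authors' value table.

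The fourth question was how Kasalath differed from Nipponbare, which shared 3 arrays at 28 days. OsMADS56 was lower in Kasalath (adjusted p = 4.16e-12), with a mean log2 signal of 6.54 against 13.63 in Nipponbare. The Kasalath signal lay close to background and was well above it in 1 of 3 samples, so no exact fold is given. The signal difference bounds the transcript difference only if the probe reads both varieties equally well, which was not tested. Hd16, a casein kinase that delays flowering, was lower in Kasalath by 3.26-fold (-1.71 ± 0.08, adjusted p = 1.12e-10), PBZ1 by 4.18-fold (-2.06 ± 0.38) and OsMADS50 by 1.51-fold (-0.60 ± 0.17). The differences of OsCCA1/LHY (-0.98 ± 0.32), OsLUX/PCL1 (-0.87 ± 0.29), DVR (-1.03 ± 0.34) and the chitinase CHT1 (Os06t0726200, -0.88 ± 0.25) were also called. PAL was higher in Kasalath by 3.11 ± 0.89 (8.63-fold, adjusted p = 0.0162) and Ehd2/RID1 by 0.47 ± 0.10 (adjusted p = 0.0027), although the latter was well above background in 1 of 3 Nipponbare samples. With no dye correction Ehd2/RID1 (0.33 ± 0.13, adjusted p = 0.176), PAL (2.36 ± 0.51, 0.0521) and OsLUX/PCL1 (-0.68 ± 0.22, 0.125) were not called. That fit used the 3 variety arrays alone, so its spread changed too. OsCCA1/LHY was not called on the processed signals (-0.93 ± 0.36, 0.0644) or in the authors' value table (-0.90 ± 0.37, 0.0909). All of these differences, before those alternatives, had the same sign on 3 of 3 arrays. OsGI at 0.01 ± 0.28 and OsPRR1/TOC1 at 0.03 ± 0.28 were not called, and Hd3a was not well above background in any sample of either variety.

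By list, 3 of 7 flowering genes were lower and 1 higher in Kasalath, 2 of 9 clock genes were lower, 4 of 8 antenna genes were lower, with a list median of -1.45, and 2 of 10 Calvin cycle, 1 of 7 chlorophyll synthesis and 3 of 16 starch and sucrose genes were lower. Of the defence list 1 of 11 was higher and 2 were lower, of the drought and cold list 1 of 5 was higher, and of the phenylpropanoid list 1 of 4 was higher. No gene of the heat stress, nitrogen, photoreceptor, redox or senescence lists with a matched probe was called. In the authors' value table SALT was at -4.62 ± 0.81, and higher in Kasalath were LEA3 of the drought and cold list by 2.58 ± 0.53, HSP101 of the heat stress list by 2.27 ± 0.59 (adjusted p = 0.00957) and the clock gene OsPRR73 by 0.66 ± 0.18 (adjusted p = 0.0153). The antenna genes without a matched probe were not called there by limma (-1.28 to 0.18, lowest adjusted p = 0.062). Of such Calvin cycle genes, 1 without a checked name was called, at -2.36 ± 0.55 (adjusted p = 0.00474), and the others were not. Outside the lists, Os05t0202800 was higher in Kasalath by 6.32 ± 0.80 (80.1-fold) and Os10t0569800 at least 35.4-fold, while Os11t0311100 and Os04t0340800 were at -7.89 ± 0.13 and -7.82 ± 0.21.

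**Figure D4:**
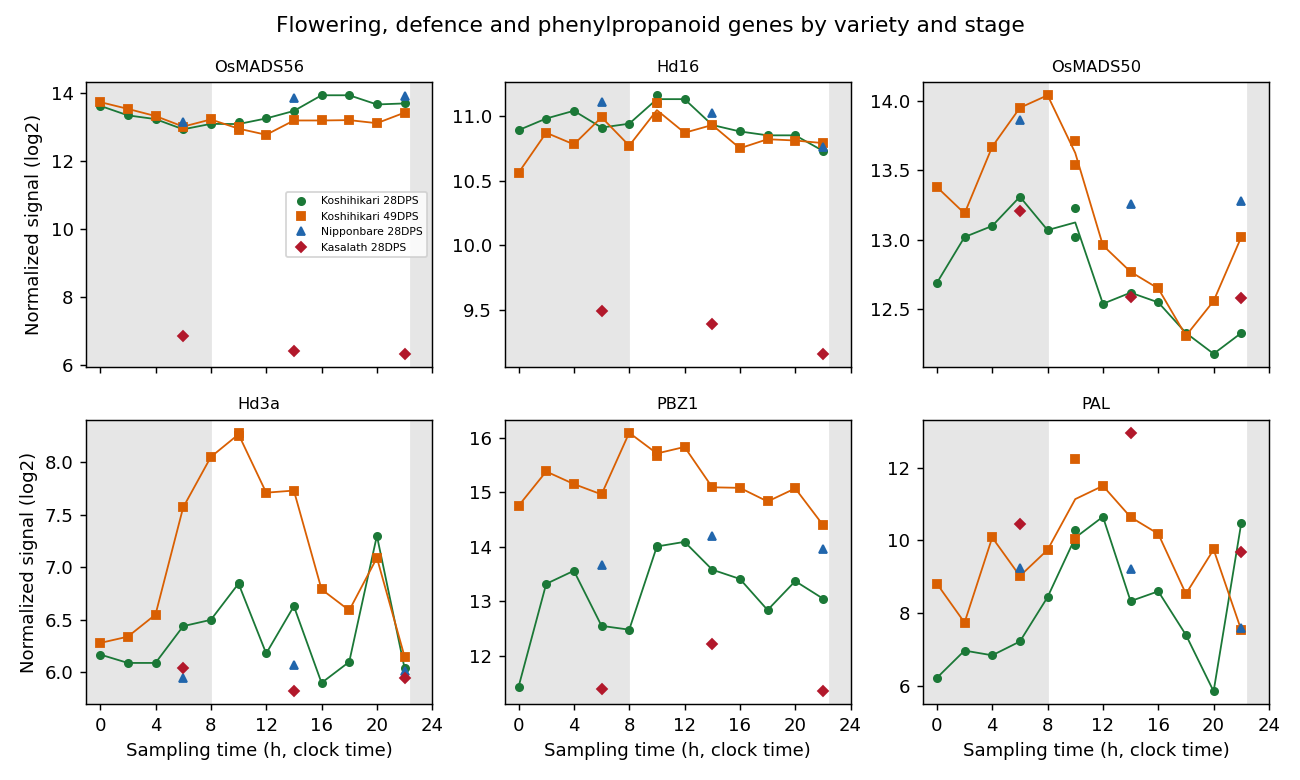
Normalized log2 signal (vertical axes) of 6 named genes against clock time in hours (horizontal axes), 1 point per sample, in Koshihikari at 28 and 49 days past sowing and in Nipponbare and Kasalath at 28 days, with the dark period in grey. The 3 Kasalath points of OsMADS56 lie between 6.34 and 6.87, and the 3 Nipponbare points between 13.14 and 13.91.

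Limma called 2884 of 11019 genes between Kasalath and Nipponbare, 1181 higher and 1703 lower in Kasalath, of which 360 and 926 by at least 2-fold. No list was called by camera, and antenna genes had an adjusted p = 0.122. The antenna list was called with median centring (adjusted p = 0.0136) and over genes well above background in all channels (0.0458), and in the other scaling and filter settings its adjusted p lay between 0.0578 and 0.150. With an estimated correlation its adjusted p = 0.891. Adjusted over the list alone, 6 antenna genes, 2 starch and sucrose genes and no Calvin cycle or chlorophyll synthesis gene were called lower. Kasalath was always labelled with Cy5, and without the dye effect learned from Koshihikari 1514 genes were called. That fit also took its spread from the 3 variety arrays alone, so the lower count cannot be put down to the dye effect alone. The share of calls that were higher in Kasalath was 41.0%, against 51.5% on the processed signals, where the median difference of all genes was 0.124, and 53.2% in the authors' value table, where it was 0.118. DVR (-0.90 to -1.10), OsMADS50 (-0.58 to -0.61) and OsCCA1/LHY (-0.87 to -1.08) kept similar sizes but lost their calls whichever of the 3 arrays was left out, and PAL lost its call without the 14:00 array (adjusted p = 0.124), CHT1 without the 6:00 array (0.0685) and with the brightest probe per gene (-0.42 ± 0.25, adjusted p = 0.252), and OsLUX/PCL1 without the 22:00 array (0.157) or the 6:00 array (0.154).

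The difference between Kasalath and Nipponbare was also called as varying with time of day in some genes. OsMADS56 was among them, with an adjusted p of 0.0219, but its Kasalath signal was close to background at all 3 times, and no tested named clock gene was, with the lowest adjusted p among them at 0.330 for OsPRR95. Limma called 241 of 11017 genes, and 55 when only genes well above background in all channels were tested. The spread came from the Koshihikari arrays alone, since each variety had 1 sample per time.

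The last question was how the 2 japonica varieties differed at 28 days, over the 3 matched times in the Cy3 channel. Outside the lists, Os02t0615800 was at least 297-fold higher in Nipponbare (adjusted p = 0.0015) and Os11t0550800 at least 262-fold (adjusted p = 0.00529), while Os12t0228800 and Os01t0872900 were at -3.82 ± 0.18 and -2.22 ± 0.16. No tested member of any list was called. OsMADS50 was at 0.71 ± 0.13 (adjusted p = 0.268) and was called with the separate-channel model (0.69 ± 0.13, adjusted p = 0.001). OsMADS15 (Os07t0108900), a MADS gene of the flowering list, was at 0.42 ± 0.15 and was called with the 10:00 slide difference subtracted (0.71 ± 0.15, adjusted p = 0.0349), while OsMADS56 was at 0.27 ± 0.11 and Hd16 at 0.11 ± 0.11. That subtraction takes the difference between a pair of arrays from all 3 pairs without counting its error. The standard error and adjusted p of the OsMADS15 call are therefore too small. The clock genes OsCCA1/LHY at 0.19 ± 0.15, OsGI at 0.21 ± 0.15 and OsLUX/PCL1 at 0.49 ± 0.19 were not called, and the clock list as a whole had a median of 0.19 (camera adjusted p = 0.364). The Calvin cycle list, with a median of -0.13, was called by camera over genes well above background in all channels (adjusted p = 0.0383) and not otherwise (0.210 over all genes). These values rest on the preset correlation. With the estimated correlation, 0.807, its camera adjusted p over all genes was 0.981. Adjusted over the list alone, 2 defence, 1 starch and sucrose and 2 flowering genes passed.

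Limma called 46 of 11019 genes, 41 higher and 5 lower in Nipponbare, all by at least 2-fold. The separate-channel model called 375 genes, 297 higher and 78 lower, and subtracting the 10:00 difference between slides called 3060, 1770 higher and 1290 lower. The count was 11 without the 14:00 pair, 169 without the 22:00 pair and 11 without the 6:00 pair. The Nipponbare samples were on slide 4 and the Koshihikari samples compared with them on slides 1, 2 and 3, so slide and variety could not be separated in this test, and the second 10:00 Koshihikari array was the only Koshihikari array on slide 4. The share of calls that were higher was 89.1%, against 71.9% when arrays were centred on their median, which moved the median difference of all genes from 0.05 to -0.08, and 100% in the authors' value table.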

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

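The tests of slide batches by the other varieties and of dye bias were chosen after the result was seen, and the others were chosen before their own values were computed but after the counts of called genes were known. The stage difference in Koshihikari was called as varying with time of day in 819 genes, and that between Kasalath and Nipponbare in 241 genes, each by a test of the difference itself. With slide-by-stage terms the 819 became 0, so slide-wide shifts stay possible. The 241 rest on the spread of the Koshihikari arrays, and became 55 over genes well above background in all channels. A 24 h rhythm appeared outside the gene table: of 90418 probes with no gene identifier that were bright enough to test, 57159 (63.2%) were called rhythmic, 22739 of them with a range of at least 2-fold, and there were no control samples to set against them.

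Random regroupings of the samples were counted for each comparison. For rhythm 1 of 100 splits, the real one, called as many genes (7392, highest other 1151), for stage 1 of 100 (6698, highest other 4) and for stage by time 1 of 100 (819, highest other 1), so free random assignment alone was excluded for these 3. These splits did not keep the times of a slide together, so they do not bear on slide-wide shifts. For Kasalath minus Nipponbare 1 of 4 splits (2884, highest other 4), for its dependence on time 4 of 4 (241, highest other 2980) and for Nipponbare minus Koshihikari 1 of 4 (46, highest other 0) gave as many genes, and the splits were too few for a share under 0.05. The 2980 genes point to a structure of the samples, since swapping the varieties on 1 array moves their constant difference into the time terms.

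The 24 h rhythm of Koshihikari was weighed against slide batches, because each slide held consecutive times. Slide batches would not be repeated in samples on another slide, yet across 7390 called genes the differences between 6:00, 14:00 and 22:00 in Koshihikari correlated with those in the other varieties on slide 4 at r = 0.865. Curves fitted without a slide predicted the differences between times within it with slopes of 0.904, 0.712 and 0.756 for slides 1, 2 and 3, so that slide-wide shifts alone are excluded by the lowest slope, 0.712. The tests bear on the called genes as a set, and a contribution of slides to single genes stays open. A daily cycle set by light or by the clock may underlie the rhythm, and which of these is untested.

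The stage difference by time of day was weighed in the same way, and it cannot be told apart from slide-wide shifts. The slope was 0.0513 over 27 genes for slide 1 and 0.810 over 50 genes for slide 2, and no gene passed the selection for slide 3. With slide-by-stage terms, Hd3a (Os06t0157700) went from 1.58 ± 0.14 to 1.75 ± 0.29 and OsMADS56 (Os10t0536100) from 0.87 ± 0.13 to 0.94 ± 0.27, so that their calls ended with larger errors and not with smaller differences, while OsGI (Os01t0182600) went from 1.05 ± 0.23 to 0.07 ± 0.26. A shift of the daily curve with age stays open as untested.

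Genes at least 2-fold lower in Kasalath outnumbered those at least 2-fold higher, 926 against 360, and by less on the scanner software's processed signals, 1223 against 839, and in the authors' value table, 1212 against 912. Among genes with more than 1 probe, probes lay over 1 log2 unit apart in 57 of 112 lower genes (50.9%) and in 8 of 40 higher genes (20.0%), a difference of 30.9 points (95% interval 15.4 to 46.4, Fisher's exact test, two-sided, p = 0.000736), against 5 of 126 genes (3.97%) that changed 2-fold between stages. A candidate explanation for part of the excess is Kasalath sequence that differs from the probes, and a gene read by 1 probe, such as OsMADS56, may be affected too. The genes were not matched for size of difference or brightness. A dim probe that reaches the floor also opens a gap, so these shares cannot tell probe mismatch from lower transcript levels. Dye bias as the whole cause is argued against by the excess that stayed after each gene's dye effect, learned from Koshihikari, was removed, 926 against 360. The counts with no dye correction, 797 against 285, came from a fit of the 3 variety arrays alone. Dye bias could also give that excess, so those counts do not bear on it. The median of the dye effect over the uncorrected log ratio, -0.0189, was taken over genes called after that removal and decides nothing by itself. Lower transcript levels in Kasalath stay open as untested.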

How the results depend on the processing

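The rhythm test on called genes of at least 2-fold range and the fits without the 12:00 array were chosen after the result was seen. The rhythm count stayed within 1.5 times its value in 14 of 15 settings (5716 to 8006 genes), the stage count in 14 of 15 (4500 to 8004), Kasalath minus Nipponbare in 10 of 11 (1948 to 3445), its dependence on time in 6 of 7 (171 to 337), stage by time in 7 of 10 (635 to 903) and Nipponbare minus Koshihikari in 4 of 12 (38 to 46). Some of this agreement was fixed in advance. Median centring of log ratios leaves average intensities, and so the rhythm fit, unchanged. Centring average intensities leaves log ratios unchanged, and so the fits of stage, stage by time and Kasalath minus Nipponbare.

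Outside these ranges, slide as a fixed block gave 4778 rhythmic genes, and slide 2 alone gave 1840 genes for stage, from 4 arrays. Stage by time fell to 539 genes on the scanner software's processed signals, 489 in the authors' value table and 0 by limma with slide-by-stage terms, where 1433 had an unadjusted p below 0.05 and 3 terms took up degrees of freedom. Kasalath minus Nipponbare gave 1514 genes with no dye correction, which uses 3 arrays alone, and 2342 to 2435, inside its range, with 1 array left out. Its dependence on time gave 55 genes when all channels had to be well above background, where 8146 genes were tested. Nipponbare minus Koshihikari gave 89 genes with average intensities centred on the median, 10 with all channels above background, 20 in the authors' value table, 375 with the separate-channel model, 11 to 169 with 1 pair left out, and 3060 with the 10:00 slide difference subtracted, which takes 1 array difference from all 3 pairs without counting its error. Apart from these constructions the cause was not tested.

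For gene lists, rhythm lists numbered 3 in the authors' value table and 4 when ranges of at least 2-fold were counted, against 0, and stage and variety lists numbered 0 with the estimated correlation, against 4, and 6 with all channels well above background, where the antenna list for Kasalath and the Calvin cycle list for Nipponbare were added. For stage OsGI, not called over all arrays, was called with the opposite sign within slide 1, at 0.41, and was called at -0.65 within slide 3. Hd16 reversed to 0.28 with median centring, and DPE2 to 0.19 and CESA7 to 0.13 within slide 3. Os02t0685200, whose difference between Nipponbare and Koshihikari was 0, moved to 1.95 with the 10:00 difference subtracted. The cause was not tested.

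Of 503 values of the 34 genes named for rhythm, 474 kept direction and side of the threshold and 29 lost the call. For stage it was 515 of 590 values of 40 genes, with 67 calls lost, 4 gained and 4 reversed. For Kasalath minus Nipponbare it was 189 of 212, with 23 lost, and for stage by time 62 of 88, with 26 lost. These tallies also count the centring settings that could not change the fit in question. Direction was not compared where neither the main fit nor the alternative called a gene. None of the 16 genes named for Nipponbare minus Koshihikari was called in the main fit. There 182 of 185 values stayed uncalled, which says nothing of their direction. Signal over background limits dim genes such as Hd3a, which was well above background in 1 of 13 samples at 28 days, so that its differences depend on the offset.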

Other observations

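The values in this part were chosen after the data were seen, and none was tested. The 10:00 Koshihikari arrays on slides 1 and 4 correlated at r = 0.987 in mean intensity, and the standard deviation of their log2 difference was 0.37, against 0.44 between 10:00 and 12:00 and 1.04 between 10:00 and 22:00. The stage differences of these arrays correlated at r = 0.658. Across 7390 rhythmic genes, the differences between 6:00, 14:00 and 22:00 in Koshihikari at 28 days correlated with those in Nipponbare at r = 0.858 and with those in Kasalath at r = 0.803. Over 1318 genes with 2 probes, the probes correlated at r = 0.911 for the stage difference and at r = 0.708 for Kasalath minus Nipponbare. Among called genes outside the lists that were well above background in at least 50% of the samples compared, Os05t0202800 had the highest difference both for stage, 4.35, and for Kasalath minus Nipponbare, 6.32. On 1 array 36080 probes had other names, with the same sequences.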
